A study of Homo sapiens with 24 samples.

How the data were processed

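RNA bound to the RNA-binding protein HuR was measured in BEAS-2B cells, a line of human bronchial epithelial cells. Per the labels' protocols, cells were left untreated (PBS) or given TNFα and IFNγ, each at 50 ng/ml, for 3 h or 18 h. Lysates were immunoprecipitated with the anti-HuR antibody 3A2 or with an IgG1 isotype control, and the recovered RNA was turned into 33P-labelled cDNA and hybridised to a membrane array of genes of autoimmunity and inflammation. The 24 arrays form 8 groups of 3, one for each combination of agent, time and antibody. The arrays of a group carry the replicate numbers 1, 3 and 4, called set 1, set 3 and set 4 here. The design text states 3 biological replicates.

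The deposited table used here holds 1 intensity per probe and array, in whole numbers, which its file name calls non-normalized. Image analysis and the treatment of background are not given in the sources used here. Of 384 probes, 355 carry values. The 29 others, which are 9 gene probes, 8 control spots and all 12 housekeeping spots, hold no value in any array. A second deposited table holds the same intensity values multiplied by 1 factor per array, from 0.542 to 3.64. The largest departure from a single factor was 2.90 intensity units, and what sets the factor is not given in the sources used here. Gene names follow the deposited accession of each probe, looked up in the gene table of assembly GRCh38.p14, which was used for names only. That gave a current symbol for 342 of the 355 measured probes, 40 of which differ from the symbol in the file, and the other 13 keep the file's symbol. Positions on the membrane and in the genome are not given in the sources used here.

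Array medians ran from 2303 to 23848 intensity units. Each array was therefore put on the log2 scale and centred on its own median over the 355 gene probes, so that every value compares a transcript with the middle transcript of the same array. A shift shared by most transcripts of an immunoprecipitate cannot be seen on this scale. The middle transcript lay near the lowest intensity on many arrays, so values of dim transcripts may hold mostly background. Linear models were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per group and no block, and genes with a Benjamini-Hochberg adjusted p under 0.05 over the 355 genes were counted as passing. Errors are standard errors (SE) of the fit or standard deviations (SD) over 3 arrays, and intervals are 95% confidence intervals of the fit. The number of arrays limits the precision.

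There were 12 comparisons. The HuR immunoprecipitate (HuR IP) was compared with the IgG1 control immunoprecipitate (IgG1 IP) in each of the 4 conditions and as their mean. The change of that ratio with stimulation was tested at 3 h, at 18 h and between both times. The last 4 comparisons set stimulated against untreated cells within each antibody and time. Comparisons within a condition share arrays with others and are not independent of them. The genes named in the text follow from 1 rule: genes that passed, up to 12 in each direction, or the 10 with the smallest p where fewer than 5 passed, together with 17 measured transcripts of chemokines, cytokines and adhesion molecules fixed in advance and up to 4 members of each list that passed. ELAVL1, which encodes HuR, and CXCL9 and PTGS2 were on the same list and have no value here. Genes that passed only under an alternative are named beside it outside this rule, as are some genes in the additional observations. Of the genes that passed, 1 is not reported here by name or value and is left out of the plot of stimulated changes.

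Of 17 fixed gene lists, 14 had at least 5 measured members. They were CC chemokines, the other chemokines (CXC, CX3C and XC), chemokine receptors, genes inducible by IFNγ, genes inducible by NF-κB, described HuR ligands and mRNAs bearing AU-rich elements, interleukins, interleukin receptors, TNF superfamily ligands, TNF receptors, Toll-like receptors with their adaptors, components of the NF-κB pathway, adhesion molecules and leukocyte markers. The list of described HuR ligands and mRNAs bearing AU-rich elements is called described HuR ligands below, though a member may be on it for its AU-rich element alone. Complement had 2 measured members and was not tested, and epithelial markers and housekeeping genes had 0. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 14 lists of a comparison. The same test with an estimated correlation, and fry, which asks whether the genes of a list move one way without comparing them with other genes, stand beside it. The lists overlap: CCL2, for example, is on the CC chemokine list and on both inducible lists. The series title names chemokine transcripts as targets, so the chemokine lists are not independent evidence of a direction in these samples. The lists, the comparisons, the rule for named genes and most alternatives were chosen before the data were examined.

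Whether the replicate numbers pair the arrays was checked from deviations from the group means, since no label states what a number stands for. Of 84 pairs of arrays of the same number, 82 had a correlation above 0.1, and among arrays of other groups each of the 24 arrays correlated best with one of its own number. All pairs passed in 8 of the comparisons. In HuR IP against IgG1 IP of stimulated cells at 18 h, 1 of 3 pairs (set 3) had a correlation of 0.0334, so that the numbers pair the arrays there, in the change of the ratio at 18 h, in the mean over conditions and in the difference between times only in part. The fit with the replicate number as a block is given beside a result where it changes it. A block on the pair within each condition was also fitted.

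The steps were tested on simulated data. Changes were planted in the comparison of HuR IP with IgG1 IP of stimulated cells at 18 h. In each of 40 simulations, 60 of the 355 genes were changed. Without a block, 48.8% of genes changed 2-fold, 84.5% of those changed 4-fold and 93.4% of those changed 8-fold were recovered, with 0.625 false calls per simulation. With the replicate block these shares were 70.4%, 94.1% and 98.9%, with 2.10 false calls. All of these shares hold for the simulated spread only. Real genes whose ratio differs between sets may be recovered less often.

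The alternatives were quantile normalization, no normalization, z scores per array, the second deposited table, normexp background correction with an offset of 50, 100 added to every intensity, the brighter probes only, only the groups compared, array weights, both blocks and leaving out each array. Leaving out a whole set of 8 arrays, and quantile or normexp values with a block, were added after seeing the data. Centring on housekeeping genes was not run, because none has a value. Figures were drawn with matplotlib 3.10.9.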

Results

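HuR is an RNA-binding protein that attaches to AU-rich elements, which many transcripts of cytokines and chemokines carry. The arrays measured 355 transcripts of immunity and signalling in RNA recovered with an anti-HuR antibody or with an IgG1 isotype control from untreated BEAS-2B cells and from cells given TNFα and IFNγ. Each of the 8 groups held 3 arrays, 1 from each of sets 1, 3 and 4, and the median array intensity ran from 2303 to 23848. Set 1 stood apart: across genes, log2 values of arrays of the same set had a median correlation of 0.750, set 3 against set 4 of 0.766, and set 1 against sets 3 and 4 of 0.394. Genes are not independent replicates in these correlations. The first principal component, which parted set 1 from the others, held 42.0% of the variance.

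In the HuR IP, transcripts of CXCL8 and IRF1 rose after 3 h of TNFα and IFNγ. CXCL8, which encodes a chemokine that draws neutrophils, rose by 3.93 ± 0.88 on the log2 scale (SE, n = 3 arrays per group, 15.2-fold, adjusted p = 0.0486), from 0.27 ± 0.70 to 4.19 ± 1.86 relative to the array median (SD). IRF1, a transcription factor induced by interferon, rose by 2.75 ± 0.51 (6.72-fold, adjusted p = 0.0125). These were the 2 genes of 355 that passed, and limma gave 17 at an unadjusted p under 0.05, 14 of them higher. IL6 stood at 1.64 ± 0.38 (adjusted p = 0.0520), TNFAIP3 at 1.52 ± 0.44 and IL1A at 1.36 ± 0.39 (adjusted p = 0.116 for both), below the threshold. The same held for ICAM1 with 3.38, CCL2 with 3.34, CXCL10 with 3.12, CXCL2 with 3.06, CXCL1 with 3.04 and CCL8 with 2.96, whose adjusted p lay between 0.106 and 0.277. CCL5 gave 0.05 ± 0.69. With the replicate block 8 genes passed, which added CCL8, CXCL1, CXCL2, ICAM1, IL1A and IL6. CXCL8 did not pass when only these 6 arrays were fitted, and IRF1 did not without normalization. None passed without set 3 or without set 4, and 19 passed without set 1. Of the single arrays, leaving out the stimulated HuR array of set 1 gave 6 genes, and leaving out any of the other 5 gave 0.

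Genes inducible by NF-κB were higher as a list in the HuR IP at 3 h, with a median of 0.51 and 29 of 33 members above 0 (adjusted p = 4.74e-20, and adjusted p = 0.00171 with an estimated correlation). Of these genes 2 passed over all genes and 10 adjusted over the list alone. Genes inducible by IFNγ had a median of 1.27 (adjusted p = 3.04e-10, and 0.0176 with an estimated correlation), with 1 of 13 over all genes and 5 adjusted over the list alone. The CXC, CX3C and XC chemokines had a median of 0.32 (adjusted p = 6.74e-06, and 0.0176 with an estimated correlation), with 1 of 13 and 4 adjusted over the list alone. Described HuR ligands had a median of 0.03 and a mean of 0.51, so that a few members carried the test (adjusted p = 0.000209, and 0.0260 with an estimated correlation), with 1 of 29 and 6 adjusted over the list alone. CC chemokines (median 0.07, adjusted p = 0.00434) and interleukins (median -0.05, mean 0.21, higher in the test, adjusted p = 0.0365) had adjusted p = 0.376 and adjusted p = 0.519 with an estimated correlation. Of the 20 CC chemokines 0 passed over all genes and 2 adjusted over the list alone, and of the 20 interleukins 0 and 3. The interleukins did not pass with the replicate block (adjusted p = 0.0570), nor did the HuR ligands with the block and an estimated correlation together (adjusted p = 0.0858). The series title names chemokines as targets, so both chemokine lists are not independent evidence.

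The IgG1 IP gives the background for these values, and there CXCL8, IRF1, IL6 and TNFAIP3 rose at 3 h. CXCL8 rose by 4.00 ± 0.88 (SE, n = 3 arrays per group, 16.0-fold, adjusted p = 0.0267), from 0.17 ± 0.44 to 4.17 ± 2.19 relative to the array median (SD). IRF1 rose by 2.69 ± 0.51 (6.43-fold, adjusted p = 0.0162), IL6 by 1.84 ± 0.38 (3.58-fold, adjusted p = 0.0248) and TNFAIP3, which encodes an inhibitor of NF-κB signalling, by 1.82 ± 0.44 (3.54-fold, adjusted p = 0.0484). No other gene passed, and 20 had an unadjusted p under 0.05. CCL2 stood at 3.61 (adjusted p = 0.0530), ICAM1 at 3.48 (adjusted p = 0.0752) and CCL8 at 3.09 (adjusted p = 0.151). The replicate block gave 9 genes, adding CCL2, CCL8, CXCL1, ICAM1 and NFKBIA. IL6 and TNFAIP3 did not pass with normexp or in the second deposited table, and without normalization only CXCL8 did. Without set 1 there were 17, without set 3 or set 4 none, and none when only these 6 arrays were fitted. Leaving out the untreated IgG1 array of set 1, 3 or 4 gave 0, 0 and 2 genes, and the stimulated array 9, 0 and 0. The difference between both IPs in this change was -0.08 ± 1.24 for CXCL8, 0.06 ± 0.72 for IRF1, -0.20 ± 0.54 for IL6 and -0.30 ± 0.62 for TNFAIP3 (adjusted p = 0.999 for each).

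As lists, genes inducible by NF-κB (median 0.45, adjusted p = 1.11e-22) and by IFNγ (median 1.23, adjusted p = 1.34e-10) were higher in the IgG1 IP at 3 h. Both held with an estimated correlation (adjusted p = 0.000810 and 0.0230). Of the 33 genes inducible by NF-κB 4 passed over all genes and 10 adjusted over the list alone, and of the 13 inducible by IFNγ 1 and 5. The CXC, CX3C and XC chemokines (median 0.08, adjusted p = 0.000747), described HuR ligands (median -0.02, mean 0.50, adjusted p = 0.00343) and components of the NF-κB pathway (median 0.04, adjusted p = 0.00343) had adjusted p = 0.0671, 0.0901 and 0.648 with an estimated correlation. Adjusted over the list alone, 4 of the 13 chemokines, 5 of the 29 HuR ligands and 1 of the 26 pathway components passed, against 1, 2 and 1 over all genes.

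**Figure D1:**
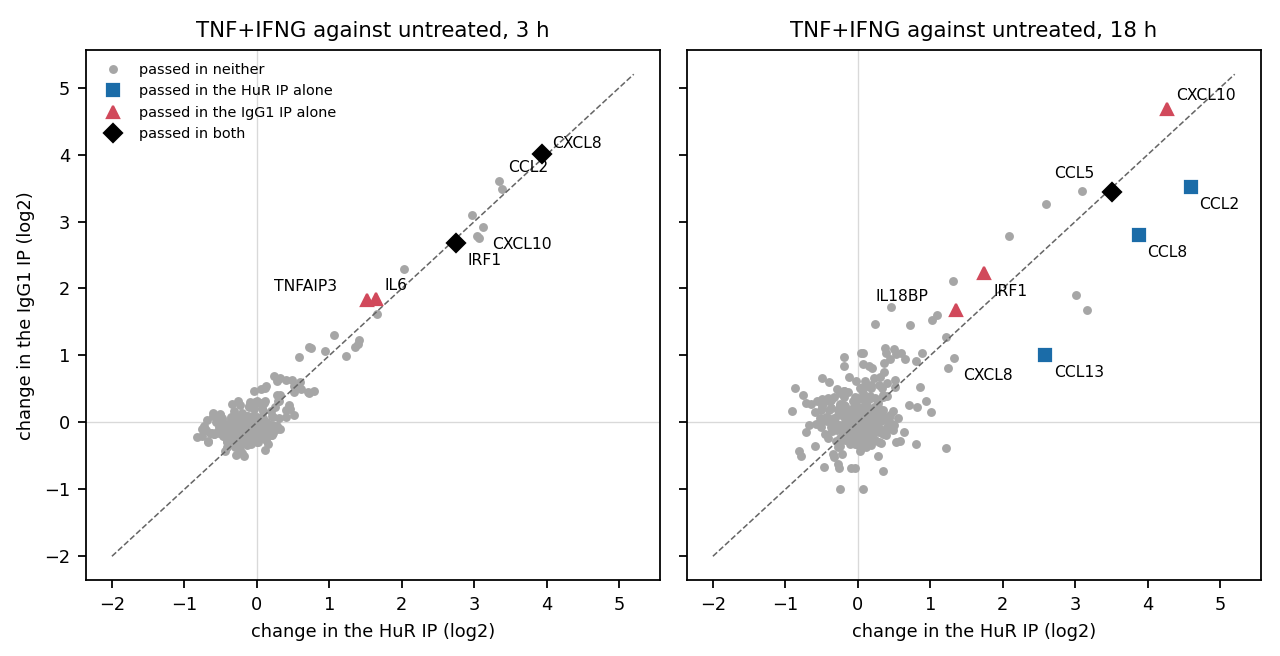
Change with TNFα and IFNγ in the HuR IP (x axis, log2) against the IgG1 IP (y axis, log2), one point per gene, at 3 h and 18 h, with markers for where a gene passed and the dashed line where both changes are equal. CXCL8 and IRF1 lie near the line at 3 h (3.93 and 4.00, 2.75 and 2.69), and at 18 h CCL5 does (3.50 and 3.44).

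At 18 h of stimulation, transcripts of CCL2, CCL5, CCL8 and CCL13, all of which encode chemokines that draw monocytes or T cells, rose in the HuR IP. CCL2 rose by 4.59 ± 0.90 (SE, n = 3 arrays per group, 24.1-fold, adjusted p = 0.0128), from 1.78 ± 1.02 to 6.37 ± 1.44 relative to the array median (SD). CCL5 rose by 3.50 ± 0.69 (11.3-fold, adjusted p = 0.0128), CCL8 by 3.87 ± 0.90 (14.7-fold, adjusted p = 0.0452) and CCL13 by 2.58 ± 0.61 (5.97-fold, adjusted p = 0.0452). These 4 were the genes that passed, and 21 had an unadjusted p under 0.05. CXCL10 at 4.26 ± 1.08 and IL18BP at 1.35 ± 0.34 did not pass (adjusted p = 0.0516 for both), nor did CXCL2 at 3.17 (adjusted p = 0.0674), IRF1 at 1.74 and CXCL1 at 3.01 (adjusted p = 0.125 for both). CXCL8 stood at 1.33 ± 0.88. The replicate block gave 13 genes, among them CXCL1, CXCL10, CXCL2, ICAM1, IL18BP, IL6, IRF1 and NFKBIA. CCL13 did not pass without normalization or with array weights, nor did CCL2 and CCL13 when only these 6 arrays were fitted. Of the sets, leaving out set 3 or set 4 gave no gene and leaving out set 1 gave 10 higher, with IL18 lower. Of the single arrays, leaving out the untreated HuR array of set 1, 3 or 4 gave 1, 0 and 1 genes, and the stimulated HuR array 1, 9 and 0.

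Genes inducible by IFNγ were higher as a list in the HuR IP at 18 h, with a median of 1.94 and all 13 above 0 (adjusted p = 8.72e-17, and 0.00475 with an estimated correlation). Of the 13, 3 passed over all genes and 10 adjusted over the list alone. CC chemokines had a median of 0.29 with 19 of 20 above 0 (adjusted p = 4.89e-10, and 0.0214 with an estimated correlation), with 4 over all genes and 5 adjusted over the list alone, though the series title names them as targets. Genes inducible by NF-κB had a median of 0.50 (adjusted p = 4.66e-10, and 0.0214 with an estimated correlation), with 2 of 33 and 8 adjusted over the list alone. The CXC, CX3C and XC chemokines had a median of 0.28 (adjusted p = 9.07e-05, and 0.0258 with an estimated correlation), with 0 of 13 and 4 adjusted over the list alone. With the block and an estimated correlation together, adjusted p was 0.0830 for CC chemokines and 0.0555 for the NF-κB list and for the other chemokines. Described HuR ligands did not pass at 18 h (median 0.10, adjusted p = 0.401).

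In the IgG1 IP at 18 h, CCL5, CXCL10, IRF1 and IL18BP rose, all of them transcripts that interferon or TNFα induces in many cells. CXCL10 rose by 4.68 ± 1.08 (SE, n = 3 arrays per group, 25.6-fold, adjusted p = 0.0259), from -0.22 ± 0.16 to 4.47 ± 2.95 relative to the array median (SD). CCL5 rose by 3.44 ± 0.69 (10.9-fold, adjusted p = 0.0168), IRF1 by 2.23 ± 0.51 (4.68-fold, adjusted p = 0.0259) and IL18BP by 1.68 ± 0.34 (3.19-fold, adjusted p = 0.0168). In all 5 genes passed, and 22 had an unadjusted p under 0.05. CCL2 stood at 3.52 ± 0.90 (adjusted p = 0.0562), CXCL11 at 3.45 (adjusted p = 0.127), ICAM1 at 3.26 (adjusted p = 0.113) and CCL8 at 2.80 (adjusted p = 0.182). With the replicate block 18 genes passed, which added CFB, C3, CCL2, CCL8, CDKN1A, CXCL11, ICAM1, IL15RA, IL6, JAK2, NFKB2, NFKBIA and RELA. There were 24 without set 1, and none without set 3, without set 4, without normalization, in the second deposited table or when only these 6 arrays were fitted. Leaving out any 1 array gave 0 genes, apart from the stimulated array of set 1, without which 18 passed. The difference between both IPs was 1.08 ± 1.27 for CCL2, 1.08 ± 1.28 for CCL8, 1.57 ± 0.87 for CCL13, 0.06 ± 0.97 for CCL5, -0.42 ± 1.52 for CXCL10, -0.48 ± 0.72 for IRF1 and -0.33 ± 0.48 for IL18BP (adjusted p = 0.994 for each).

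Genes inducible by IFNγ were higher as a list in the IgG1 IP at 18 h (median 2.70, adjusted p = 9.65e-15, and 0.00925 with an estimated correlation), with 4 of 13 over all genes and 8 adjusted over the list alone. For genes inducible by NF-κB (median 0.63, adjusted p = 6.41e-07) the estimated correlation gave adjusted p = 0.105, with 2 of 33 over all genes and 6 adjusted over the list alone. Components of the NF-κB pathway (median 0.23, adjusted p = 0.0339, and 0.67 with an estimated correlation) had 0 of 26 either way, and with the replicate block 3 over all genes and 5 adjusted over the list alone. The direction of this list turned to lower without set 3 (adjusted p = 0.914). CC chemokines had a median of -0.01 and a mean of 0.51 (adjusted p = 0.485), with 1 of 20 over all genes and 3 adjusted over the list alone.

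**Figure D2:**
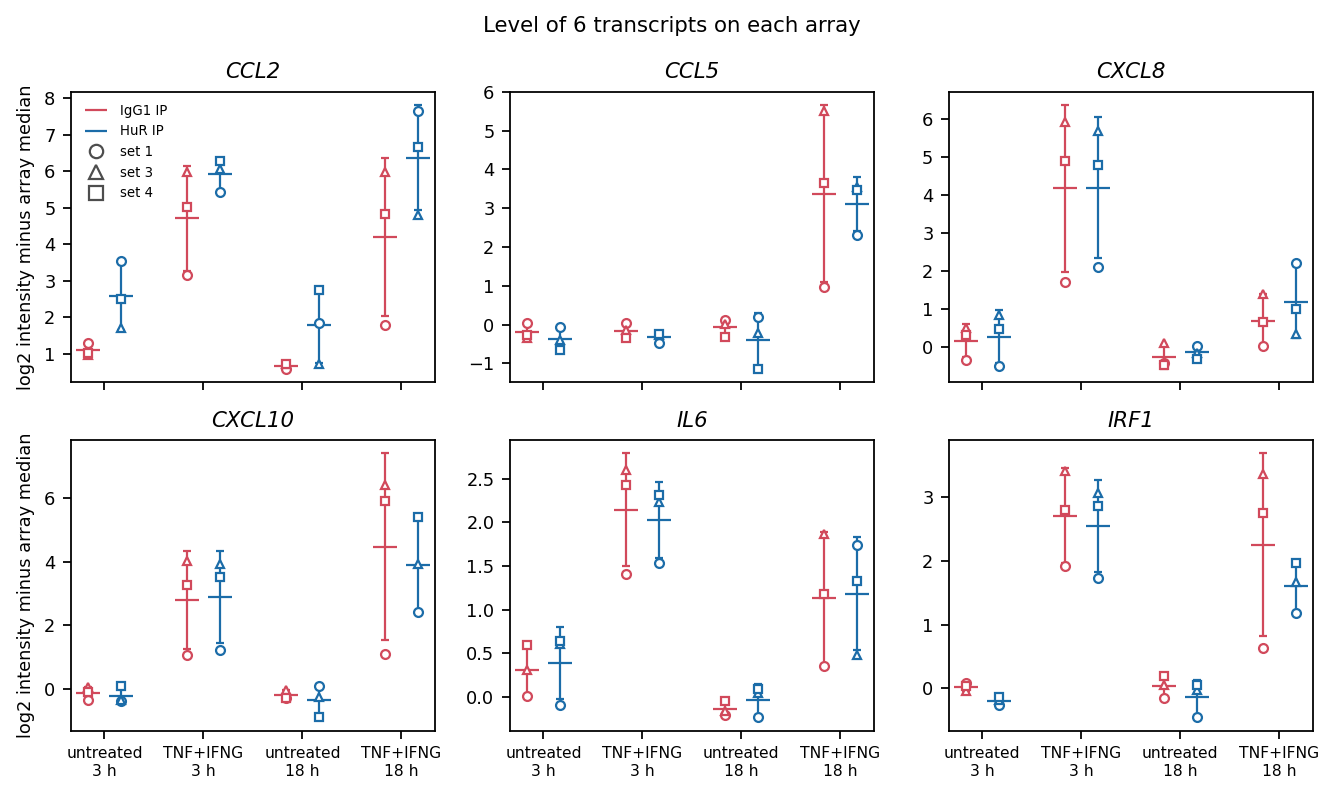
Levels of 6 transcripts in the 8 groups as log2 intensity minus the array median, with the mean and SD over 3 arrays and each array by set (IgG1 IP in red, HuR IP in blue). CXCL8 is highest after 3 h of stimulation in both IPs (4.17 in the IgG1 IP and 4.19 in the HuR IP) and CCL2 at 18 h in the HuR IP (6.37).

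The question of which transcripts HuR binds is put by the HuR IP against the IgG1 IP, and no transcript passed in any condition or in the mean over the 4 conditions. In that mean JUND, a subunit of the transcription factor AP-1, led with 1.63 ± 0.48 (SE, n = 12 arrays per antibody, adjusted p = 0.446), and CCL2 followed with 1.49 ± 0.45 (adjusted p = 0.446). These SE count 12 ratios that come from 3 sets and are not independent, and over the 3 set means the SE was 1.12 for JUND and 0.87 for CCL2. MAX stood at 0.92 ± 0.29, ATF2 at 1.01 ± 0.32 and RUNX1 at 0.87 ± 0.28. CCL2 was above 0 in 11 of the 12 pairs of HuR and IgG1 arrays, and JUND, MAX and ATF2 in 10 of 12. MAPK8, TGIF1, BMPR2 and PPP3R1 lay between 0.62 and 0.93, and NFATC2IP at -0.19 ± 0.08. The ratio differed between sets: for CCL2 it was 2.91 in set 1, -0.09 in set 3 and 1.65 in set 4, and for JUND 3.67, -0.18 and 1.39. Among chemokine and cytokine transcripts, CXCL1 stood at 0.79 ± 0.44, CCL8 at 0.78 ± 0.45, CXCL2 at 0.70 ± 0.42, CXCL8 at 0.18 ± 0.44, IL6 at 0.03 ± 0.19 and TNF at -0.03 ± 0.27 (adjusted p = 0.992 for each). In this mean limma counted 0 genes at an adjusted p under 0.05 and 12 at an unadjusted p under 0.05, 10 of them higher, and 33 unadjusted with the replicate block. CCL2 passed in the z scores, CCL2 and JUND in the second deposited table, and quantile normalization with the replicate block gave 12 higher and 3 lower. Quantile values with the block within conditions gave 2, CCL8 and PPP3R1, and neither block allows for a ratio shared by the conditions of a set.

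The list of described HuR ligands and mRNAs bearing AU-rich elements had 29 measured members. Its median ratio was -0.06 in the mean over conditions, with 10 above 0 (adjusted p = 0.633, and 0 adjusted over the list alone). JUND, CCL2, MAX, ATF2 and RUNX1, which led that mean, are not on this list, so it does not speak for every transcript that HuR may bind. None of the 14 lists passed there, with adjusted p from 0.284 to 0.914. Genes inducible by IFNγ had 0 of 13 over all genes and 1, CCL2, adjusted over the list alone, with a median of -0.13 and a mean of 0.06. For the other lists the median was -0.03 in CC chemokines (mean 0.11), 0.03 in the other chemokines, -0.10 in chemokine receptors, -0.10 in genes inducible by NF-κB, -0.06 in interleukins and -0.03 in interleukin receptors. It was -0.04 in TNF superfamily ligands, 0.12 in TNF receptors, -0.02 in Toll-like receptors with their adaptors, -0.07 in components of the NF-κB pathway, -0.05 in adhesion molecules and -0.03 in leukocyte markers.

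**Figure D3:**
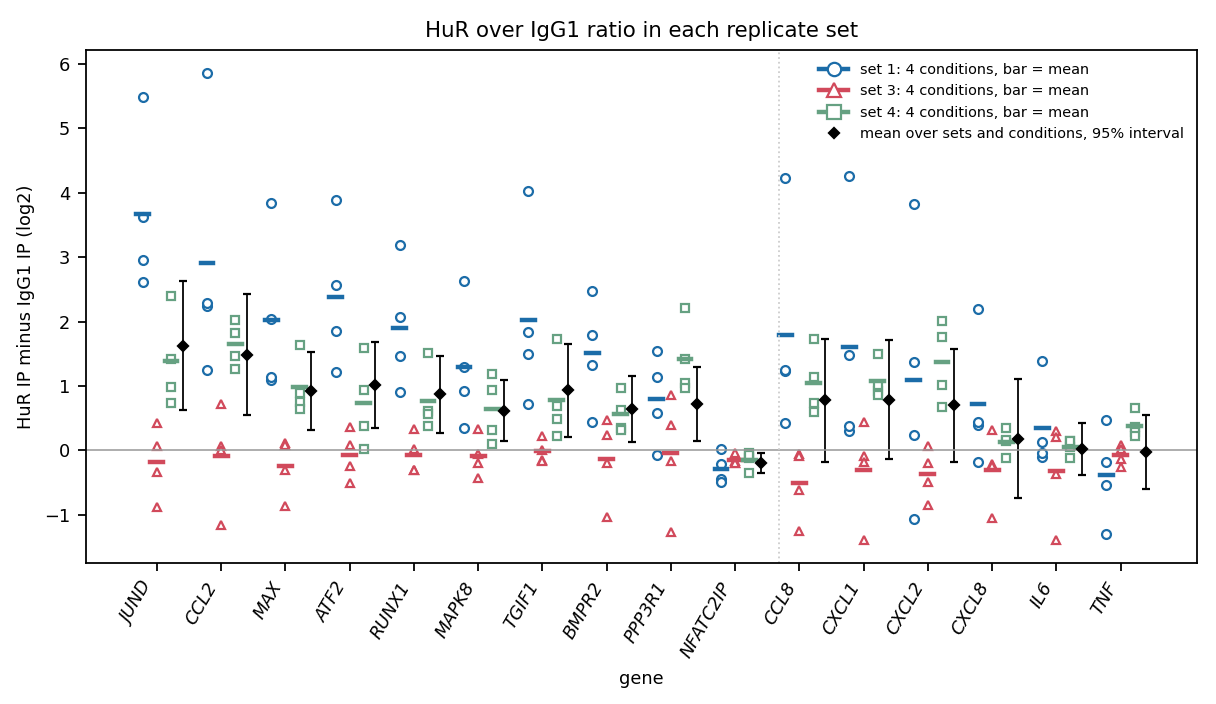
HuR IP minus IgG1 IP (log2) for 16 transcripts, one point per condition and set, with a bar for the mean of a set and a diamond for the mean over sets with the 95% confidence interval of the fit, which counts the 4 conditions of a set as independent. In set 1 most named transcripts lie above 0, such as CCL2 with a mean of 2.91, and in set 3 the means of all 16 lie below 0, from -0.50 for CCL8 to -0.01 for TGIF1.

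In stimulated cells at 18 h, CC chemokines were higher as a list in the HuR IP than in the IgG1 IP, and components of the NF-κB pathway were lower. CC chemokines had a median ratio of 0.19 with 16 of 20 above 0 (adjusted p = 4.53e-05, and 0.457 with an estimated correlation), and the pathway components a median of -0.26 with 4 of 26 above 0 (adjusted p = 0.00587, and 0.861 with an estimated correlation). No member of either list passed over all genes or adjusted over the list alone. CCL2 stood at 2.17 ± 0.90, CCL13 at 1.53 ± 0.61, CCL20 at 0.84 ± 0.31, CCL8 at 1.57 ± 0.90 and CCL19 at 0.48 ± 0.23, and in the other direction CDKN1A at -1.34 ± 0.58 and CD3G at -1.78 ± 0.81 (SE, n = 3 arrays per group, adjusted p = 0.990 for each). The sets differed widely: in sets 1, 3 and 4 the level of CCL2 was 7.64, 4.81 and 6.67 in the HuR IP. In the IgG1 IP it was 1.79, 5.97 and 4.84. The ratio of CCL2 was thus largest in set 1, where its IgG1 value was lowest, and below 0 in set 3. Among the pathway components NFKBIB stood at -0.44, NFKB2 at -0.39, RELB at -0.38 and NFKB1 at -0.32. Over all genes limma gave 0 here, against 11 at an unadjusted p under 0.05 and 32 unadjusted with the replicate block. Quantile values with either block gave 1 gene that passed, which was higher. The second deposited table gave 25 genes that passed, all higher, where the median of all genes lay at 1.61. The CC chemokines did not pass without set 1 (adjusted p = 0.0589), and the pathway components did not pass without set 3 (0.846), in quantile values (0.438) or in the second deposited table (0.221). With the replicate block CD3G was lower adjusted over the list of leukocyte markers alone.

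In untreated cells at 3 h, CC chemokines and chemokine receptors were lower as lists in the HuR IP than in the IgG1 IP. The medians were -0.17 for CC chemokines, 5 of 20 above 0 (adjusted p = 0.0194, and 0.671 with an estimated correlation), and -0.15 for the receptors, 2 of 16 above 0 (adjusted p = 0.00925, and 0.671 with an estimated correlation), with 0 members of either adjusted over the list alone. CCL2 ran against its list with 1.48 ± 0.90, and CXCR4 stood at -0.38 ± 0.19. The CC chemokines did not pass in quantile values (adjusted p = 0.881), in the second deposited table (0.382) or without set 3 (0.692), nor did the receptors in quantile values (0.0712). The 8 TNF receptors had a median of 0.31, all above 0 (adjusted p = 0.0665, and 0.0115 with the replicate block, where the estimated correlation gave adjusted p = 0.568). Most members of these lists are numbered near others of their family, and an effect of probe position on the shifts was not tested. Among single genes PPP3R1 led with 1.15 ± 0.55 (adjusted p = 0.999), and limma gave 0 genes and 1 at an unadjusted p under 0.05.

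In stimulated cells at 3 h and in untreated cells at 18 h no gene and no list passed. At 3 h IL19 stood at 0.49 ± 0.27, CCL19 at 0.39 ± 0.23 and CCL2 at 1.21 ± 0.90 (SE, n = 3 arrays per group, adjusted p = 0.999 for each). At 18 h ATF2 stood at 1.27 ± 0.64, JUND at 1.69 ± 0.95 and CCL2 at 1.10 ± 0.90 (adjusted p = 0.999 for each). Both limma fits gave 0 genes at an unadjusted p under 0.05, and 1 and 4 with the replicate block. CC chemokines had a median of -0.03 and a mean of 0.11 at 3 h (adjusted p = 0.826) and -0.12 at 18 h (adjusted p = 0.22), and described HuR ligands -0.03 (adjusted p = 0.889) and -0.05 (adjusted p = 0.278).

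Whether stimulation shifts transcripts onto HuR is asked by the change of the ratio of HuR IP to IgG1 IP, and no single transcript passed. At 18 h CC chemokines were higher as a list, with a median of 0.38 and all 20 above 0 (adjusted p = 7.56e-07, and 0.201 with an estimated correlation), and 0 passed adjusted over the list alone. As targets named in the series title, they are not independent evidence. CCL13 stood at 1.57 ± 0.87, CCL20 at 0.85 ± 0.44, CCL21 at 0.44 ± 0.27 and CCL19 at 0.54 ± 0.33 (SE, n = 3 arrays per group, adjusted p = 0.994 for each). CXCL2 stood at 1.49 ± 1.19, CXCL1 at 1.10 ± 1.25 and IL6 at -0.05 ± 0.54. With the replicate block the other chemokines (median 0.33, adjusted p = 0.0360, against 0.1 without it) and components of the NF-κB pathway (median -0.19, adjusted p = 0.0480, against 0.0574) passed too, but the estimated correlation with the block gave adjusted p = 0.517 and 0.872. The replicate numbers pair the arrays only in part here. The CC chemokine list passed in quantile values, in the second deposited table, with the replicate block and without any single set. By set its median was 0.06 in set 1, 0.13 in set 3 and 0.63 in set 4. For single genes limma counted 0, 0 at an unadjusted p under 0.05 as well, and 16 unadjusted with the replicate block.

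At 3 h the change of the ratio was higher for CC chemokines (median 0.22, 16 of 20 above 0, adjusted p = 0.00107) and chemokine receptors (median 0.20, 13 of 16 above 0, adjusted p = 0.0167), and lower for components of the NF-κB pathway (median -0.19, 5 of 26 above 0, adjusted p = 0.0187). With an estimated correlation each had adjusted p = 0.526. None of the 3 passed in quantile values (adjusted p = 0.258, 0.185 and 0.258) or without set 1 (0.0665, 0.161 and 0.161), and 0 of their members passed adjusted over the list alone. The receptors did not pass without set 3 (0.0868), nor did the pathway components without set 3 (0.315), without set 4 (0.0563) or in the second deposited table (0.102). IL2 led the single genes with 0.48 ± 0.37, CCL21 stood at 0.29 ± 0.27 and CCL2 at -0.27 ± 1.27 (SE, n = 3 arrays per group, adjusted p = 0.999 for each). Here limma gave 0 genes, and 0 at an unadjusted p under 0.05 with or without the replicate block.

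Between both times the change of the ratio was higher at 18 h for CC chemokines (median 0.23, 14 of 20 above 0, adjusted p = 0.0366, and 0.804 with an estimated correlation), 0 of them adjusted over the list alone. This list did not pass with the replicate block (adjusted p = 0.145), in quantile values (0.0601), in the second deposited table (0.0703) or without set 4 (0.751). VAV1, a signalling protein of blood cells, led with 1.02 ± 0.62, CCL13 stood at 1.35 ± 1.23, CCL15 at 0.59 ± 0.56 and CCL2 at 1.35 ± 1.79 (SE, n = 3 arrays per group, adjusted p = 0.997 for each). The limma fit gave 0 genes, and 0 at an unadjusted p under 0.05 with or without the replicate block.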

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

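The tests of array background, of exchanged labels in stimulated cells at 18 h alone and of other splits of the arrays were chosen before their results were seen, and the other tests here only after the result was seen.

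The ratio of HuR IP to IgG1 IP differed between stimulated and untreated cells, by a test of the difference itself, for 3 lists at 3 h and 1 at 18 h. All rest on camera with its preset correlation, and with an estimated correlation the adjusted p was 0.526 for the 3 lists at 3 h, 0.201 at 18 h and 0.804 for the list that differed between times. At 3 h the median log2 difference was 0.22 for CC chemokines, 0.20 for chemokine receptors and -0.19 for components of the NF-κB pathway, and none of the 3 passed in quantile values (adjusted p = 0.258, 0.185 and 0.258). At 18 h it was 0.38 for CC chemokines, and between both times 0.23 for the same list. In set 1 the median of the CC chemokines was -0.09 at 3 h with 10 of 20 above 0, and at 18 h it was 0.06 with 11 of 20 above 0, while set 3 gave 0.24 and 0.13 with 13 above 0 at both times and set 4 0.26 and 0.63 with 18 and 19 above 0.

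The ratio of HuR IP to IgG1 IP differed between the sets. For the 20 genes with the highest ratio in set 1, a choice that fixes the value of set 1 in part, the median over the 4 conditions was 1.47 in set 1, -0.17 in set 3 and 0.69 in set 4. HuR and IgG1 arrays of 1 condition correlated across genes at 0.919 to 0.984 in set 3 and 0.877 to 0.975 in set 4, against 0.463 to 0.826 in set 1. By that measure set 1 stood apart and set 3 lay close to set 4. For array background that compresses the ratios of set 3, the median after normexp was set against that of set 1. It stayed at -0.085 (95% bootstrap interval -0.22 to 0.03) in set 3, against 2.14 in set 1 and 0.93 in set 4. This goes against compression that normexp can undo. Normexp estimates background from the intensities alone, so other compression stays open. A ratio particular to set 1 was argued against by 0.69 in set 4 (interval 0.31 to 0.97, 19 of 20 above 0). The bootstrap intervals here resample the 20 genes, which share the arrays of 1 set and are not independent. They do not measure the spread between sets. Labels exchanged in all of set 3, with ratios as strong as in set 4, were argued against by its untreated cells. The median there was 0.15 (interval 0.02 to 0.22, 14 of 20 above 0, and 0.21 with normexp) against 0.83 in set 4. In quantile values it was -0.06 with 8 of 20 above 0, against 0.46 in set 4. The sign turns there, so an exchange together with a weaker immunoprecipitation stays open. For labels exchanged in stimulated cells at 18 h alone the test used quantile values, because the 2 arrays differ in spread (SD 1.43 and 0.75). It gave 0.28 (interval 0.09 to 0.53) in set 3, which goes against an exchange. The median there was -0.86 after centring with 1 of 20 above 0 and -0.37 with normexp, against 0.80 and 1.24 in set 4, which is the sign an exchange gives. The sign turns with the normalization, so this exchange stays open. An exchange in stimulated cells at 3 h alone (-0.22 in set 3 after centring with 3 of 20 above 0, -0.01 in quantile values and -0.28 with normexp, against 0.42, 0.24 and 0.72 in set 4) was not tested apart from these values and stays open, as does a weaker immunoprecipitation in set 3, for which no measure is given. A weaker immunoprecipitation alone would give ratios near 0, which the interval with normexp allows. After centring, however, 2 of the 20 genes lay above 0 in the mean over conditions of set 3. Across all genes, that mean correlated at -0.171 with set 1 and -0.241 with set 4. The means of set 1 and set 4 correlated at 0.441, with a Spearman rho of 0.161. No biological explanation was tested, because no group of the design parts the sets.

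At 18 h in the HuR IP CCL19, whose probe is numbered next to that of CCL2, stood at 0.50 without passing (adjusted p = 0.781), and of the 12 CC chemokine probes away from CCL2 and on neither inducible list 11 lay above 0 too. Probe numbers were used, since the layout of the membrane is not given in the sources used here. Signal that spreads between neighbouring spots is a candidate explanation: the deviations of consecutive probes with unrelated names correlated at 0.168 over 147 pairs, above the highest value of 0.112 among spacings of 3 to 20. For CCL2 itself the test was open, with a slope of CCL19 on CCL2 of 0.059 between the median of -0.01 and the 95th percentile of 0.15 over 312 genes, and slopes of 0.12 for CCL20, numbered next to CCL2 on the other side, and 0.02 for CCL21 at a distance of 2. Binding of related cDNA by CC chemokine probes is open too, with a median of 0.18 (bootstrap interval over probes 0.12 to 0.30) in those 12 probes against 0.50 for CCL19. A change of the transcripts themselves was not tested apart from these. Probes are numbered in the order of the file's symbols, so position may also add to the shifts of family lists, which was not tested. In set 4 the mean ratio was 0.85 for TNFRSF1B. Of the probes that follow in that order, TRPV6 stood at 0.86, TYK2 at 0.87 and VAV1 at -0.03.

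CXCL8 and IRF1, which rose with TNFα and IFNγ in the HuR IP at 3 h, also rose in the IgG1 IP. RNA carried onto the control beads in proportion to its abundance may account for this at 3 h, where the orthogonal slope of the IgG1 change on the HuR change over all genes was 0.957 (0.831 to 1.07 with 1 set left out, r = 0.913 across genes, which are not independent). At 18 h the slope was 0.998 with a wider range of 0.682 to 1.30 and r = 0.756. By rank the correlation over genes was lower, with a Spearman rho of 0.410 at 3 h and 0.256 at 18 h. The slopes may therefore rest on the strongly changed genes and do not show that most transcripts follow this proportion. None of the 24 arrays holds RNA from before immunoprecipitation, so abundance itself was not measured in them, and a change of the transcript level in the cells, which the groups of the design name, stays open as its source.

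The genes with an adjusted p under 0.05 were compared with other splits of the same 6 arrays, of which there are 10, too few for a share under 0.05. The real count and the highest other were 2 and 0 for the stimulated change in the HuR IP at 3 h, 4 and 6 in the HuR IP at 18 h, 4 and 0 in the IgG1 IP at 3 h, and 5 and 1 in the IgG1 IP at 18 h. For HuR IP against IgG1 IP, genes at an unadjusted p under 0.05 were counted, and the real count and the highest other were 1 and 13 in untreated cells at 3 h, 0 and 32 in stimulated cells at 3 h, 0 and 54 in untreated cells at 18 h, and 11 and 64 in stimulated cells at 18 h. No split can give fewer than 0, so the 2 comparisons with a real count of 0 decide nothing. Of 100 groupings drawn for the mean over the 4 conditions, 42 gave as many as the real 12, with a highest other of 86, so that chance was not excluded there. These draws shuffled the arrays of a condition without parting the pairs of a set, so their counts hold differences between sets too. For the change of the ratio at 3 h, at 18 h and between both times the real count was 0. All 100 groupings must give as many as 0, so these draws decide nothing, and their highest counts were 70, 96 and 116. In each of the 4 conditions the split with the most genes (13, 32, 54 and 64) put both arrays of a set on the same side, which points to the sets as a structure of the samples. Among the 4 splits of 6 arrays that part all 3 pairs, as the real one does, the highest other count was 0 in the HuR IP at both times and in the IgG1 IP at 3 h, and 1 in the IgG1 IP at 18 h, and for the ratio in the 4 conditions in the order above it was 2, 2, 18 and 33.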

How the results depend on the processing

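Fits without a whole set, and quantile or normexp values with a block, were chosen after seeing the data, and all other alternatives before. Under all of them together, 604 values of gene and list counts stayed within 1.5 times the reported count and 124 moved. Counts of 0 that stayed 0 are among the 604, and the reported gene count was 0 in every comparison of HuR IP with IgG1 IP and in every change of the ratio. Of the values of named genes, 7352 kept their direction and their side of the threshold, 276 came to pass, 133 no longer passed and 669 changed sign. Most of the 7352 belong to genes that did not pass in the first place. These totals therefore do not measure how stable the passing genes are. None of the 15 named gene values that passed changed sign under any alternative. Among all 321 named gene values, 150 changed sign under some alternative, 98 of them under an alternative with all arrays and 127 when arrays were left out, and the highest absolute log2 value to do so with all arrays was 1.34. Z scores were brought back to log2 units with the mean SD of the arrays. Genes outside the brighter probes have no value under that alternative, array weights were fitted with a warning that their tolerance was not reached, and centring on housekeeping genes was not run.

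For the stimulated change in the HuR IP at 3 h, where 2 genes were higher, quantile normalization and the second deposited table gave 7 each, no normalization 1 (without IRF1), z scores and the brighter probes 6 each, only the groups compared 3 (CCL2, ICAM1 and IRF1, without CXCL8), array weights 16, the replicate block 8, quantile values with the block 15 with 2 lower, and normexp with the block 11. At 18 h in the HuR IP, where 4 were higher, quantile normalization and the second deposited table gave 9 each, z scores 8, normexp 11, the brighter probes 7, only the groups compared 2 (without CCL2 and CCL13), no normalization 4 and array weights 11 (both without CCL13), the replicate block 13, quantile values with the block 21 with 12 lower, and normexp with the block 19. In the IgG1 IP at 3 h, where 4 were higher, quantile normalization gave 7, no normalization 1 (CXCL8), z scores 7, normexp 4 and 6 in the second deposited table (both without IL6 and TNFAIP3), only the groups compared 0, array weights 17 with 1 lower, the replicate block 9, quantile values with the block 13 with 3 lower, and normexp with the block 10. In the IgG1 IP at 18 h, where 5 were higher, no normalization, the second deposited table and only the groups compared gave 0, array weights 20, the replicate block 18, quantile values with the block 15 with 6 lower, and normexp with the block 15. The block leaves each log2 value as it is and lowered the median SE from 0.317 to 0.241, which is how it adds genes, and fitting only the groups compared leaves fewer arrays for the spread. For the other alternatives the cause was not tested.

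For the HuR IP against the IgG1 IP, where 0 genes passed, the second deposited table gave 25 higher in stimulated cells at 18 h and 2 higher in the mean over conditions, z scores gave 1 higher in the mean, and quantile values with the block gave 1 higher in stimulated cells at 18 h and 12 higher and 3 lower in the mean. Quantile values with the block within conditions gave 1 and 2 higher. In the second deposited table the median of all genes lay at 1.61 in stimulated cells at 18 h against -0.03 after centring, and without normalization at 1.35, a shift of all genes that is part of those 25 values, while no normalization gave 0 genes with a like shift. The same shift was 1.99 and 1.66 for the change of the ratio at 18 h, 1.97 and 1.42 for its difference between times, -1.47 and -1.20 for the stimulated change in the IgG1 IP at 18 h, 0.54 and 0.48 in the HuR IP at 18 h, 0.25 and 0.18 for the mean ratio, and -0.36 and -0.29 for the ratio in untreated cells at 18 h. Without normalization it was also -0.24 for the ratio in untreated cells at 3 h, 0.20 for the change of the ratio at 3 h and 0.15 in the HuR IP at 3 h, and with normexp -0.20 in both IPs at 3 h. These shifts are part of the values without normalization and in the second deposited table given below.

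Of the lists, 2 passed in untreated cells at 3 h, 0 with an estimated correlation, fry or quantile normalization and 1 in the second deposited table. In stimulated cells at 18 h 2 passed, 0 with an estimated correlation or fry and 1 with quantile normalization or the second deposited table, and in untreated cells at 18 h 0 passed and 1 with quantile normalization. For the change of the ratio at 3 h 3 passed, and 0 with an estimated correlation, fry or quantile normalization. At 18 h 1 passed, 0 with an estimated correlation or fry and 3 with quantile normalization or the replicate block. Between times 1 passed, 0 with an estimated correlation, fry, the second deposited table or the replicate block and 2 with quantile normalization. For the stimulated change 6 passed in the HuR IP at 3 h and 3 with fry, 5 in the IgG1 IP at 3 h, 2 with an estimated correlation and 1 with fry, and 3 in the IgG1 IP at 18 h and 1 with an estimated correlation or fry. The replicate block changed no call beyond those named here and with the results above.

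With arrays or a set left out, the number of genes higher ran from 0 to 19 in the HuR IP at 3 h, from 0 to 10 in the HuR IP at 18 h with 0 to 1 lower (IL18, without set 1), from 0 to 17 in the IgG1 IP at 3 h and from 0 to 24 in the IgG1 IP at 18 h, with the highest counts without set 1 and 0 without set 3 or set 4. Fewer arrays account for part of the lower counts, and the cause of the higher ones was not tested. The ratio of HuR IP to IgG1 IP gave 0 genes with any array or set left out. Of the lists, 2 to 3 passed in untreated cells at 3 h, 0 to 2 in stimulated cells at 3 h, 0 to 2 in untreated cells at 18 h, 2 to 4 in stimulated cells at 18 h and 0 to 3 in the mean over conditions. For the change of the ratio these were 0 to 2 at 3 h, 2 to 4 at 18 h and 0 to 4 between times, and for the stimulated change 5 to 6 in the HuR IP at 3 h, 4 throughout in the HuR IP at 18 h, 5 to 6 in the IgG1 IP at 3 h and 2 to 4 in the IgG1 IP at 18 h. The level of background under a signal is not given in the sources used here, so how far it limits dim genes cannot be measured directly. On many arrays, however, the lowest intensity lay near the median. In untreated cells at 18 h these were 8218 and 11831 in the IgG1 array of set 1 and 3177 and 4472 in the HuR array of set 3. The HuR array of set 4 had a wider gap, 2740 and 7052. Small shifts of dim probes, and list medians that rest on them, may therefore reflect background.

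Log2 values of named genes with another sign than in the centred fit without a block are given by comparison. They belong to the alternatives and are not the results. The results have the opposite sign, and for many of these genes their values are not given in the text. Values under quantile normalization and normexp hold with a block too, and the cause was not tested apart from the shifts above. Ranges cover left-out arrays and sets.

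In the HuR IP against the IgG1 IP in untreated cells at 3 h, no normalization gave -0.15 for CXCL8, -0.16 for IL6 and -0.23 for TNF. The second deposited table gave -0.0095 for IL6 and -0.073 for TNF. Normexp gave -0.40 for CXCL8 and -0.094 for IL6. Quantile normalization gave 0.0042 for CX3CL1, -0.047 for IL6 and -0.029 for TNF. Z scores gave -0.0010 for IL6. Leaving out arrays took CXCL2 from -0.013 to 0.80, CXCL3 from -1.17 to 0.68, CXCL8 from -0.19 to 0.48, CXCL10 from -0.24 to 0.065, IL6 from -0.063 to 0.32 and TNF from -0.40 to 0.53.

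In the HuR IP against the IgG1 IP in stimulated cells at 3 h, array weights gave 0.22 for CCL7, -0.30 for CXCL3, 0.17 for CXCL11, -0.13 for CX3CL1 and 0.011 for IFNG. In the second table the values were -0.061 for CXCL8 and -0.038 for CX3CL1. Normexp gave -0.27 for CXCL3 and -0.014 for CXCL8. Quantile normalization gave -0.072 for CXCL8 and 0.071 for ICAM1. Left-out arrays took IL18R1 from -0.015 to 0.52, BMPR1B from -0.0011 to 0.58, ACVR2A from -0.030 to 0.78, CCL7 from -0.21 to 0.24, CCL8 from -0.53 to 1.18, CCL11 from -0.29 to 0.0087, CXCL1 from -0.12 to 1.38, CXCL2 from -0.0032 to 1.19, CXCL3 from -1.10 to 0.95, CXCL8 from -1.21 to 1.07, CXCL10 from -0.75 to 0.95, CXCL11 from -0.67 to 0.45, CX3CL1 from -0.18 to 0.17, IL6 from -0.49 to 0.13, TNF from -0.47 to 0.27, IFNG from -0.12 to 0.088 and ICAM1 from -1.10 to 0.39.

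In the HuR IP against the IgG1 IP in untreated cells at 18 h, array weights gave 0.023 for CCL7, 0.060 for CCL11, 0.13 for CCL20, -0.0018 for CXCL1, 0.24 for CXCL3, 0.14 for CXCL11, 0.11 for IFNG and -0.094 for ICAM1. No normalization gave -0.11 for CXCL2, -0.16 for CXCL8 and -0.18 for IL6. The second deposited table gave -0.18 for CXCL2, -0.22 for CXCL8, -0.24 for IL6 and -0.012 for ICAM1. Normexp gave 0.34 for CCL20 and 0.28 for IFNG. Quantile normalization gave 0.099 for CCL20, 0.13 for CXCL3, 0.091 for CXCL11 and 0.077 for IFNG. Z scores gave 0.12 for CCL20, 0.049 for CXCL11 and 0.070 for IFNG. Leaving out arrays took CCL5 from -0.62 to 0.051, CCL7 from -0.42 to 0.17, CCL11 from -0.38 to 0.20, CCL20 from -0.21 to 0.22, CXCL1 from -0.098 to 0.66, CXCL2 from -0.63 to 1.04, CXCL3 from -1.34 to 0.68, CXCL8 from -0.037 to 0.31, CXCL10 from -0.41 to 0.13, CXCL11 from -0.47 to 0.30, CX3CL1 from -0.40 to 0.10, TNF from -0.62 to 0.47, IFNG from -0.24 to 0.21 and ICAM1 from -0.25 to 0.69.

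In the HuR IP against the IgG1 IP in stimulated cells at 18 h, array weights gave -0.17 for IL6. No normalization gave 0.037 for CDKN1A, 1.11 for CCL5, 0.81 for CXCL10, 0.87 for CXCL11, 1.24 for CX3CL1, 1.05 for ICAM1, 0.99 for RELB, 0.98 for NFKB2, 1.05 for NFKB1 and 0.94 for NFKBIB. In the second table the values were 0.30 for CDKN1A, 1.37 for CCL5, 1.07 for CXCL10, 1.13 for CXCL11, 1.51 for CX3CL1, 1.31 for ICAM1, 1.25 for RELB, 1.24 for NFKB2, 1.31 for NFKB1 and 1.20 for NFKBIB. Normexp gave 0.057 for CCL5, 0.087 for CXCL11, -0.48 for IFNG and 0.041 for ICAM1. Quantile normalization gave -0.0044 for IFNG. Z scores gave 0.46 for CCL5, 0.29 for CXCL10, 0.25 for CXCL11, -0.040 for IFNG and 0.29 for ICAM1. 100 added to intensities gave -0.0047 for IFNG. Left-out arrays took CCL5 from -1.47 to 0.80, CXCL3 from -0.39 to 1.88, CXCL8 from -0.35 to 1.27, CXCL10 from -2.26 to 0.41, CXCL11 from -2.11 to 0.59, CX3CL1 from -0.27 to 0.027, IL6 from -0.62 to 0.77, IFNG from -0.30 to 0.26 and ICAM1 from -1.71 to 0.46.

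In the mean of the HuR IP against the IgG1 IP over conditions, array weights gave 0.097 for CCL7, -0.039 for IL6, 0.065 for TNF and 0.021 for IFNG. No normalization gave 0.017 for NFATC2IP, 0.14 for CCL7, 0.13 for CCL11, 0.040 for CXCL10, 0.11 for CX3CL1, 0.18 for TNF, 0.15 for IFNG and 0.079 for ICAM1. The second deposited table gave 0.085 for NFATC2IP, 0.038 for CCL5, 0.21 for CCL7, 0.20 for CCL11, 0.11 for CXCL10, 0.0051 for CXCL11, 0.18 for CX3CL1, 0.25 for TNF, 0.21 for IFNG and 0.15 for ICAM1. Normexp gave -0.093 for CXCL3. Quantile normalization gave 0.026 for CCL7. Z scores gave 0.091 for CXCL10. Leaving out arrays took CCL5 from -0.54 to 0.027, CCL7 from -0.12 to 0.029, CCL11 from -0.13 to 0.010, CXCL3 from -0.24 to 0.42, CXCL8 from -0.12 to 0.45, CXCL10 from -0.59 to 0.14, CXCL11 from -0.67 to 0.00021, CX3CL1 from -0.15 to 0.0092, IL6 from -0.13 to 0.20, TNF from -0.23 to 0.15, IFNG from -0.13 to 0.0011 and ICAM1 from -0.48 to 0.18.

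In the change of the ratio at 3 h, array weights gave 0.012 for CCL8, -0.20 for CXCL3, 0.16 for CXCL8, -0.0068 for CX3CL1 and 0.068 for ICAM1. No normalization gave 0.11 for CCL8, 0.16 for CXCL8, 0.038 for IL6, 0.049 for TNF and 0.13 for ICAM1. Normexp gave -0.11 for CCL5, -0.70 for CCL11, 0.38 for CXCL8 and 0.39 for ICAM1. Quantile normalization gave -0.14 for CCL5, 0.12 for CCL8, -0.21 for CCL11 and 0.38 for ICAM1. Z scores gave -0.025 for CCL5, -0.052 for CCL11, 0.070 for CXCL8 and 0.058 for ICAM1. Left-out arrays took CCL2 from -1.05 to 0.36, CCL5 from -0.23 to 0.22, CCL7 from -0.032 to 0.57, CCL8 from -1.12 to 0.59, CCL11 from -0.12 to 0.34, CXCL1 from -0.67 to 0.83, CXCL2 from -0.33 to 0.74, CXCL3 from -0.91 to 1.27, CXCL8 from -1.31 to 0.97, CXCL10 from -0.66 to 1.04, CXCL11 from -0.36 to 0.77, CX3CL1 from -0.064 to 0.26, IL6 from -0.57 to 0.050, TNF from -0.70 to 0.25, IFNG from -0.0015 to 0.29, ICAM1 from -0.88 to 0.61, CCL19 from -0.045 to 0.67 and NFKBIB from -0.60 to 0.019.

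In the change of the ratio at 18 h, array weights gave -0.30 for CCL5. No normalization gave 0.94 for FADD, 1.13 for GATA3, 0.87 for MEF2A, 1.24 for CXCL10, 1.29 for CXCL11, 1.60 for IL6 and 1.00 for ICAM1. The second deposited table gave 1.27 for FADD, 1.46 for GATA3, 1.20 for MEF2A, 1.56 for CXCL10, 1.62 for CXCL11, 1.93 for IL6 and 1.32 for ICAM1. Normexp gave 0.048 for CXCL10, 0.78 for CXCL11, -0.29 for CX3CL1 and -0.76 for IFNG. Quantile normalization gave -0.11 for CX3CL1 and -0.082 for IFNG. Z scores gave 0.34 for CXCL10, 0.20 for CXCL11, 0.026 for IL6, -0.11 for IFNG and 0.19 for ICAM1. Leaving out arrays took CCL2 from -0.68 to 2.20, CCL5 from -1.15 to 1.13, CCL8 from -0.28 to 2.19, CXCL1 from -0.29 to 2.25, CXCL2 from -0.20 to 2.57, CXCL8 from -0.31 to 0.96, CXCL10 from -2.11 to 0.56, CXCL11 from -1.96 to 0.73, CX3CL1 from -0.27 to 0.36, IL6 from -0.79 to 0.72, TNF from -0.25 to 0.86, IFNG from -0.31 to 0.50 and ICAM1 from -2.05 to 0.049.

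In the difference of that change between times, array weights gave -0.51 for CCL5, -0.097 for CCL7, -0.041 for CCL11, -0.15 for CXCL8, 0.064 for CX3CL1 and -0.069 for IL6. No normalization gave 0.86 for GATA3, 0.74 for FADD, 0.82 for MECOM, 0.96 for ICOS, 0.83 for IL2, 0.80 for CXCL10, 0.88 for CXCL11, 1.36 for CX3CL1, 1.30 for IFNG and 0.87 for ICAM1. In the second table the values were 1.41 for GATA3, 1.30 for FADD, 1.38 for MECOM, 1.52 for ICOS, 1.38 for IL2, 1.35 for CXCL10, 1.44 for CXCL11, 1.91 for CX3CL1, 1.85 for IFNG and 1.42 for ICAM1. Normexp gave -0.37 for CXCL8, 0.085 for CXCL11 and -0.0069 for IL6. Quantile normalization gave -0.016 for IL6. Z scores gave 0.15 for CXCL10 and 0.13 for ICAM1. Left-out arrays took TGFA from -0.099 to 1.97, CCL2 from -0.25 to 2.28, CCL5 from -1.16 to 1.11, CCL7 from -0.17 to 0.41, CCL8 from -0.085 to 2.20, CCL11 from -0.015 to 0.55, CCL20 from -0.078 to 0.75, CXCL1 from -0.15 to 1.77, CXCL2 from -0.090 to 1.97, CXCL3 from -0.19 to 2.50, CXCL8 from -0.60 to 1.68, CXCL10 from -2.31 to 0.37, CXCL11 from -2.14 to 0.55, CX3CL1 from -0.52 to 0.43, IL6 from -0.38 to 0.68, TNF from -0.14 to 1.13, IFNG from -0.38 to 0.21 and ICAM1 from -1.94 to 0.23.

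In the stimulated change in the HuR IP at 3 h, array weights gave 0.035 for CCL11. No normalization gave 0.23 for CCL11 and 0.22 for IFNG. The second deposited table gave 0.079 for CCL11 and 0.063 for IFNG. Normexp gave 0.16 for CCL11 and 0.12 for IFNG. Quantile normalization gave 0.011 for CCL11 and 0.038 for IFNG. Z scores gave 0.079 for CCL11 and 0.053 for IFNG. Leaving out arrays took CCL5 from -0.14 to 0.28, CCL7 from -0.023 to 0.37, CCL11 from -0.076 to 0.099, CXCL3 from -0.47 to 1.70, TNF from -0.24 to 0.52 and IFNG from -0.10 to 0.049.

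In the stimulated change in the HuR IP at 18 h, array weights gave -0.022 for CCL11 and -0.026 for CXCL3. No normalization gave 0.19 for TNF and 0.43 for IFNG. In the second table the values were 0.25 for TNF and 0.49 for IFNG. Normexp gave -0.090 for CX3CL1. Quantile normalization gave -0.072 for CX3CL1. Left-out arrays took CCL11 from -0.062 to 0.50, CXCL3 from -0.29 to 2.07, CX3CL1 from -0.21 to 0.34 and IFNG from -0.27 to 0.25.

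In the stimulated change in the IgG1 IP at 3 h, the second deposited table gave 0.031 for CCL11. Normexp gave 0.59 for CCL7 and 0.86 for CCL11. Quantile normalization gave 0.14 for CCL7 and 0.22 for CCL11. Z scores gave 0.067 for CCL7 and 0.13 for CCL11. Leaving out arrays took CCL5 from -0.055 to 0.16, CCL7 from -0.21 to 0.058, CCL11 from -0.25 to 0.071, CCL20 from -0.030 to 0.22, CXCL3 from -0.42 to 1.30 and TNF from -0.15 to 0.80.

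In the stimulated change in the IgG1 IP at 18 h, no normalization gave -0.95 for CCL7, -1.05 for CCL20, -0.25 for CXCL8, -0.17 for NFKB2 and -0.53 for RELB. In the second table the values were -1.22 for CCL7, -1.32 for CCL20, -0.52 for CXCL8, -0.21 for IL6, -0.44 for NFKB2 and -0.80 for RELB. Normexp gave 0.30 for CCL11, 0.20 for CX3CL1 and 0.53 for IFNG. Quantile normalization gave 0.039 for CX3CL1 and 0.030 for IFNG. Z scores gave 0.011 for CCL11, 0.018 for CX3CL1 and 0.077 for IFNG. Left-out arrays took CCL11 from -0.25 to 0.11, CXCL3 from -1.02 to 0.78, CX3CL1 from -0.069 to 0.059 and IFNG from -0.25 to 0.16.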

Other observations

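Complement transcripts were the 2 measured members of a list too short to test, and both are named here after their values were seen. In the IgG1 IP at 18 h of stimulation CFB stood at 1.53 ± 0.55 (SE, n = 3 arrays per group, adjusted p = 0.298, and 0.0158 with the replicate block) and C3 at 1.10 ± 0.44 (adjusted p = 0.440, and 0.0358 with the replicate block). In the HuR IP at 18 h CFB stood at 1.02 ± 0.55 and C3 at 0.50 ± 0.44 (adjusted p = 0.996 for both, and 0.17 and 0.635 with the replicate block).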
